A study of Mus musculus with 43 samples.

How the data were processed

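The series profiled fetal liver from mouse embryos at embryonic day E13.5, wild type (WT) or heterozygous for the Nan allele of Klf1 (Nan/+), in 43 samples that the labels place in 19 groups. Klf1 encodes EKLF, an erythroid zinc-finger transcription factor, and Nan changes a zinc finger of that factor. Chromatin immunoprecipitation (ChIP) of EKLF was analysed here from 1 peak list per genotype, each made from 3 ChIP libraries together. The series design describes these as biological replicates from littermate livers. The CBP, H3K27ac, RNA polymerase II, ATAC and input samples of the series were not analysed here on their own.

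Per the file headers, the authors called peaks with HOMER on the mm10 build, with each genotype's ChIP libraries set against input libraries. For both lists the authors used a q of 0.01, a fold of 4 and, inside HOMER, a DESeq2 step with a false discovery rate of 0.01 and a log2 fold of 2, per the file headers. Calling settings differed between the lists, per the file headers: the WT list used a peak size of 125 bp and a minimum distance of 250 bp, and the Nan/+ list 175 bp and 300 bp. In each list 2 distinct input libraries filled 3 places, 1 of them used again. The submitters' processing notes also name bcl2fastq 2.17, Bowtie2 2.1, SAMtools 1.1 and deepTools 3.5. The score column deposited by the authors held the value 1 in every row and therefore carried no measure of peak strength. Positions were read as BED intervals and are printed counted from 1.

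Per the file headers, the WT ChIP libraries held 74140385, 103170594 and 85729597 tags, and the Nan/+ ChIP libraries 85986275, 72023512 and 100763687. The mean was 87680192 ± 14613072 tags (SD, n = 3) in WT and 86257825 ± 14372012 (SD, n = 3) in Nan/+. Per the file headers, tags were counted per library for the DESeq2 step, which set ChIP against input within each genotype. The lists hold no values per replicate, so no spread between replicates could be computed. All tests below therefore compare these lists and not the genotypes, and regions are not replicates. Exact binomial (Clopper-Pearson) 95% intervals cover counting error only.

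Regions were called shared when they overlapped by at least 1 bp, and otherwise WT-only or Nan-only. The observed overlap was set against 1000 placements of the WT regions on the same chromosome with bedtools 2.31.1, leaving out the first 3 Mb of each chromosome. A second null, added after the lists were examined, shifted each WT region by 10 to 50 kb. Genes came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 renders. Of 21900 protein-coding genes, 108 placed on alternate loci and 269 on Y, the mitochondrial chromosome or unplaced sequence were left out, which left 21523. A gene had a region when a region's centre lay in its body or within 10 kb of either end, so that 1 region can belong to several neighbouring genes.

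The 17 gene lists, the tests and the rule for named genes were fixed before the data were examined. Of 311 list entries 307 matched the gene table, through symbols or older symbols, and Hbb-b1, Hbb-b2, Ahsp and Ly76 did not. List coverage was compared with 10000 random lists of protein-coding genes matched on length in 10 strata (one-sided upper p, Benjamini-Hochberg over lists and genotypes). Genes with a region in 1 genotype alone were set against an even split by the exact sign test and against other genes by Fisher's exact test (both two-sided, Benjamini-Hochberg over lists). The naming rule took the 8 leading regions of each class, up to 4 leading members of each list, up to 4 members with a region in 1 genotype alone, and Klf1, Hbb-bs, Hba-a1, Alas2, E2f2, Bcl11a, Epb42, Dmtn, Ahsp, Hamp, Irf7 and Cd44. Only some of these are named in the text. Any other gene named was chosen after its values were seen.

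Several planned steps could not be run as written. With a constant score, comparisons of peak value used region width instead, ranks for named genes used width, and alternatives based on a stricter value were replaced by width. Width depends on the calling settings, which differ between the lists. Shared and other regions were compared by width within each list, whereas the width correlation over overlapping pairs, the counts above the minimum width, equal list lengths by width and the order of the widest shared regions use the widths of both lists. The gene table gives no strand and no exons, so the planned share at transcription start sites became the share of centres within 1 kb of either end of a protein-coding gene, and exon, intron and UTR shares became shares inside genes. Motif counts and the central bases of the EKLF site need a genome sequence and were not analysed here. These replacements were chosen after the lists were examined. Width medians were compared by a two-sided permutation test with 100000 resamples. Differences in shares carry a bootstrap interval over 1 Mb windows (2000 resamples), because neighbouring regions are not independent.

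The functions were checked on the deposited regions, on random gene lists set against the deposited counts, and on simulated lists. The overlap function called 0 of 9181 WT regions differently from bedtools. Of 200 random lists, 2.0% had a coverage p under 0.05, against 95.5% of 200 lists enriched for genes with a WT region. Fisher's exact test of the split gave a p under 0.05 in 0.50% of 200 random lists, so it is conservative for lists of this size. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives covered the overlap rule, the gene region, list length, region width and the random lists.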

Results

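EKLF occupancy was mapped by ChIP in fetal liver, the main site of red cell formation at embryonic day E13.5, from WT and Nan/+ embryos. Each genotype was represented by 1 list of called regions made from 3 ChIP libraries, with summed depths of 263040576 tags in WT and 258773474 in Nan/+. The lists hold positions without a strength per region and without values per replicate, so differences between them have no replicate check. A region called in 1 list alone can lie just below the calling threshold in the other.

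The first comparison asked how far EKLF positions coincided between the genotypes. In the body and 10 kb flanks of Klf1, on chromosome 8, all 3 Nan/+ regions overlapped WT regions. Of these WT regions only the widest, at 84902476 to 84903608, lay inside the gene, and the others lay in the flanks. A further 3 WT regions had no Nan/+ counterpart, among them the region over the lower-coordinate end of the gene (84901702 to 84902307). Over the genome most positions differed. The WT list held 9181 regions and the Nan/+ list 15564, or 1.70 Nan/+ regions per WT region, although both covered a similar length, 4.27 Mb and 4.05 Mb. Of the WT regions 2250, or 24.5% (95% interval 23.6 to 25.4), overlapped a Nan/+ region, and of the Nan/+ regions 2285, or 14.7% (14.1 to 15.2), overlapped a WT region. Random placement gave a mean overlap of 0.511% of WT regions (permutation by 1000 random placements, one-sided p = 0.001, the smallest they can give). With a reciprocal overlap of at least 50%, the WT share fell to 14.3% and the Nan/+ share to 8.41%. Among the widest 50% of Nan/+ regions, which take in some regions of the minimum width, the share was 25.2%.

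Each list held 4 regions on the mitochondrial chromosome. None was filtered out here, and whether they reflect EKLF binding was not tested. Of the 8 widest shared regions, 2 lay on that chromosome, whose genes were left out, the widest of all at 2 to 6528. The others lay in Tspan32, Tspoap1, Dnajb13, Mrm1, Slc4a1, which encodes the band 3 anion exchanger (chromosome 11, 102347537 to 102351089), and Slc25a37, which encodes the mitochondrial iron importer mitoferrin (chromosome 14, 69248665 to 69254320). The widest WT-only region lay in E2f4, a cell cycle regulator (chromosome 8, 105303061 to 105306063), and another in Aurka, a mitotic kinase. Among the 8 widest Nan-only regions, 2 lay in Zfpm1, which encodes the GATA1 cofactor FOG1, and 1 each in Cmip and Ank1. Shared regions were wider than the others within each list: the median was 536 bp against 364 bp in WT, and 376 bp against 176 bp in Nan/+ (permutation p = 1e-05 in each, the smallest that 100000 resamples can give). A wider region overlaps more readily, so the overlap rule accounts for part of this, and clustering makes these p-values too small. With sharing set by centres within 250 bp, the medians were 507.5 bp against 374 bp in WT and 369 bp against 176 bp in Nan/+. In the Nan/+ list 8481 regions, or 54.5%, had the minimum width of 176 bp, and 4.13% of these were shared against 27.3% of the wider ones. Across the 2250 overlapping pairs the rank correlation of widths was 0.300, a description over regions that are not replicates.

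**Figure D1:**
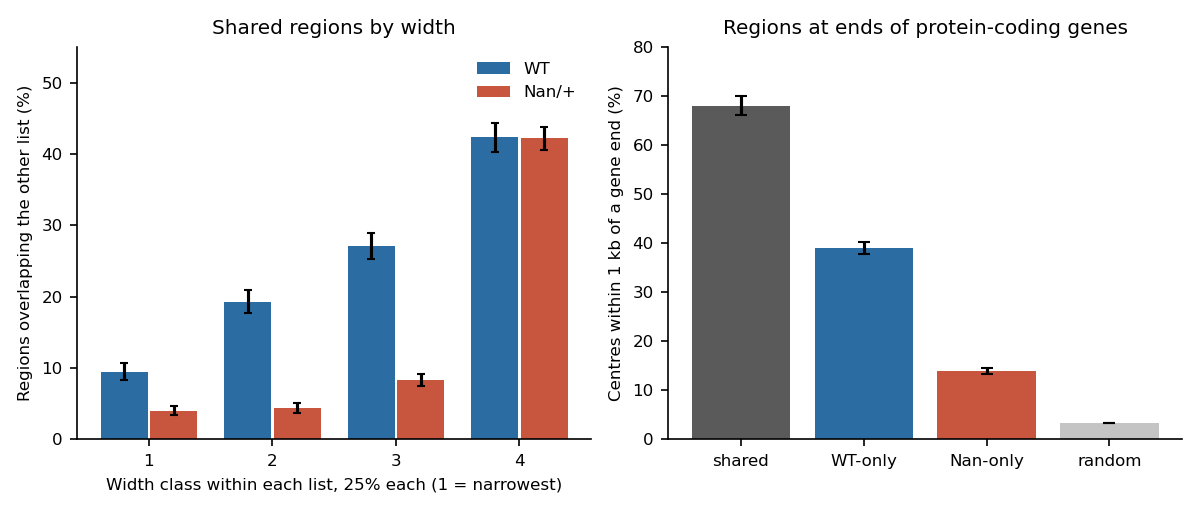
Left, the percentage of called EKLF regions that overlap the other genotype's list, by width class, each 25% of the WT or Nan/+ list; right, the percentage of region centres within 1 kb of an end of a protein-coding gene for shared, WT-only and Nan-only regions and for random positions. Bars are percentages, error bars are exact binomial 95% intervals, and the lower Nan/+ classes consist of regions of 176 bp in order of position; sharing reached 42.3% in the widest WT class and 42.2% in the widest Nan/+ class.

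The next comparison placed the regions relative to genes. Shared regions sat mostly at gene ends, 68.0% of them within 1 kb of an end of a protein-coding gene (95% interval 66.0 to 69.9), against 39.0% of WT-only regions (37.8 to 40.1), 13.9% of Nan-only regions (13.3 to 14.5) and 3.28% of random positions. WT-only regions exceeded Nan-only regions by 25.1 percentage points, with a window bootstrap interval of 23.6 to 26.6. Without Nan/+ regions of the minimum width the Nan-only share was 21.2% and this difference 17.7 points, outside that interval. Nan-only regions lay more often inside genes, 68.9% against 64.7% of WT-only regions (Fisher's exact test, adjusted p = 3.08e-09). They also lay more often over 10 kb from any protein-coding gene, 15.7% against 10.9% (Fisher's exact test, adjusted p = 6.54e-21). Regions cluster, so these p-values are too small. Window bootstrap intervals, WT-only minus Nan-only, were -5.77 to -2.615 and -5.926 to -3.609 points. Neither difference was recomputed without Nan/+ regions of the minimum width. Counted once per region, the gene around a Nan-only region had a median length of 92.1 kb, against 49.0 kb for WT-only regions. A long gene with many regions enters these medians many times. Counted once per gene, genes with a region in Nan/+ alone had a median of 30.24 kb, against 15.95 kb in WT alone. The gene table gives no strand, so starts and ends of genes are not told apart.

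The globin loci were examined in detail. At the beta-globin locus on chromosome 7, wide WT regions lay at the lower-coordinate ends of the adult genes Hbb-bt (103810481 to 103812572) and Hbb-bs (103825467 to 103826776). These overlapped Nan/+ regions, which at Hbb-bt had the minimum width of 176 bp. WT regions at the opposite ends, 103813667 to 103813970 at Hbb-bt and 103827833 to 103828324 at Hbb-bs, overlapped no Nan/+ region. In the 30 kb beyond the embryonic gene Hbb-y, the side on which the locus control region lies, 4 WT regions and 1 Nan/+ region were called and 0 were shared. At the alpha-globin locus on chromosome 11, WT regions just beyond the higher-coordinate ends of Hba-a1 (32284645 to 32285873) and Hba-a2 (32297599 to 32298534) were shared. From Hba-x to Hba-a2, with 5 kb flanks, 6 WT and 5 Nan/+ regions were called, and these 2 WT regions alone were shared. Within Nprl3, whose introns hold alpha-globin enhancers, there were 7 WT regions and 2 Nan/+ regions, with 0 shared. These segments were chosen after the lists were examined and were not tested.

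**Figure D2:**
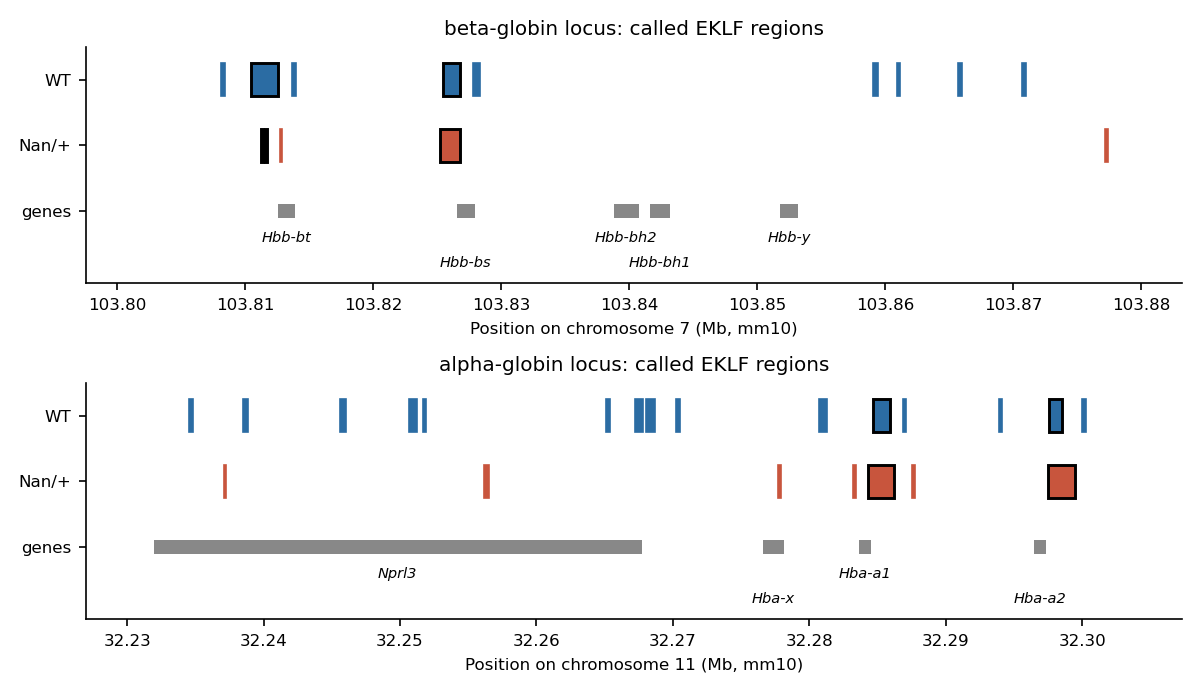
Called EKLF regions in WT and Nan/+ along the beta-globin locus on chromosome 7 and the alpha-globin locus on chromosome 11, with position in Mb on mm10 on the horizontal axis and genes in grey. Black outlines mark regions that overlap the other list, 2 WT regions in each locus.

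Genes with EKLF regions were compared next. A region was assigned to 7213 genes in WT and 8081 in Nan/+, of which 5049 had regions in both, 2164 in WT alone and 3032 in Nan/+ alone. Independence would give 2708 genes in both. That figure does not allow for gene length or for regions assigned to several neighbouring genes, so the excess over it was not tested. Counting Nan/+ regions wider than the minimum alone, WT-alone genes numbered 3310 and Nan-alone genes 1503. With gene ends within 5 kb and all regions kept, they numbered 2456 and 2208, so which genotype had more genes of its own depended on the narrow Nan/+ calls and on the gene region.

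Heme synthesis genes were covered in both lists, 14 of 15 in WT and 12 of 15 in Nan/+ (adjusted p = 0.000425 and 0.00286 against length-matched random lists). Fech, which encodes ferrochelatase, had 14 WT and 7 Nan/+ regions, and Cpox, coproporphyrinogen oxidase, had 8 and 1. Alad and Slc25a38, the latter a mitochondrial glycine carrier, had 4 and 5 WT regions and 0 in Nan/+, while Alas2, the erythroid enzyme of the first step, had 5 in each, 1 of them shared. Uros, at 3 and 6, had more in Nan/+. Red cell membrane genes were covered at 23 of 24 in both lists. Ank1, encoding ankyrin, had 32 WT and 26 Nan/+ regions, Dmtn, encoding dematin, had 10 and 1, Sptb, encoding beta-spectrin, had 15 and 21, and Epb42, encoding protein 4.2, had 1 and 2. Among iron genes 12 of 15 were covered in each list, with Tfrc, the transferrin receptor, at 7 and 4 and Steap3 at 4 and 0, against Slc11a2, a ferrous iron transporter, at 2 and 7 and Slc25a37 at 6 and 7. Blood group and surface antigen genes were covered at 11 of 16 in WT and 12 of 16 in Nan/+, with Kel at 8 and 1, Icam4 at 3 and 0 and Cd44 at 0 and 2. The Nan/+ regions at Cd44 had the minimum width of 176 bp. Globin genes were covered at 6 of 8 and 5 of 8, the latter at an adjusted p of 0.00286, or 0.200 against random lists not matched on length. These genes lie in 2 clusters, where neighbours can count the same region. Random lists take scattered genes, so the p-values for globin genes are too small.

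Of the erythroid transcription factors and cofactors, 31 of 37 had a region in WT and 34 of 37 in Nan/+. Zfpm1 had 24 and 27. Bcl11a, which encodes a repressor of embryonic globin genes, had 1 and 2 at different positions, the Nan/+ regions at the minimum width. Of the cell cycle regulators 17 of 29 and 23 of 29 had one, with E2f2, a direct EKLF target in the literature, at 8 and 1 and E2f4 at 6 and 1, whereas E2f1 and Cdk1 stood at 0 and 2. In this list 8 genes had a region in Nan/+ alone and 2 in WT alone (Fisher's exact test, adjusted p = 0.787). The 1 Nan/+ region at E2f2 overlapped the WT region at 1 end of the gene (chromosome 4, 136171945 to 136172448). The other 7 WT regions had no counterpart, among them the widest, which spanned the opposite end of the gene (136194956 to 136196327). Enucleation and autophagy genes were covered at 16 of 22 in each list. Their Nan/+ call was lost with gene ends within 5 kb (9 of 22, adjusted p = 0.229), with equal list lengths by width (11 of 22, adjusted p = 0.0554) and with Nan/+ regions above the minimum width (9 of 22, adjusted p = 0.156). Of the Pol II pausing genes 18 of 26 and 21 of 26 had a region, and of the acetyltransferase and chromatin genes 18 of 18 and 16 of 18. In both lists 11 of the 17 gene lists lay above length-matched random lists at an adjusted p under 0.05. Housekeeping genes were 1 of them, with 10 of 15 in WT and 11 of 15 in Nan/+ (adjusted p = 0.0110 and 0.00286), so coverage above random lists was not particular to erythroid genes; with gene ends within 5 kb their WT count was 8 of 15, at an adjusted p of 0.0547.

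**Figure D3:**
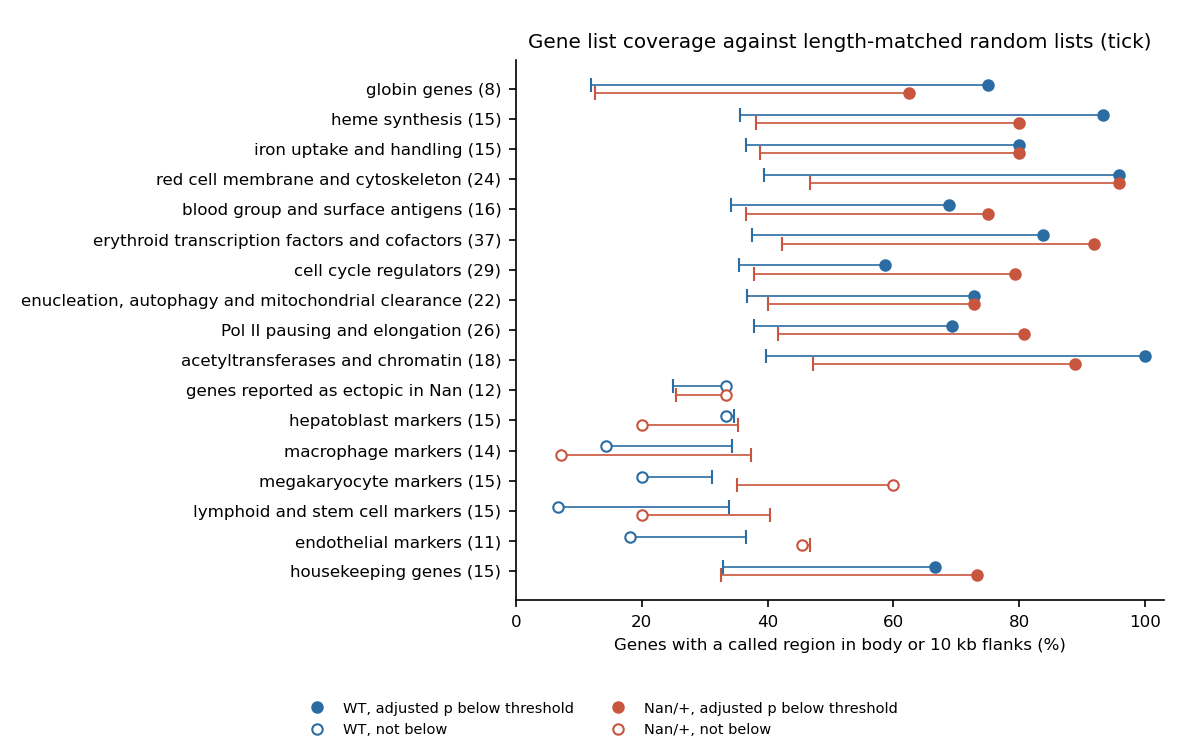
Percentage of each gene list with a called EKLF region in the gene body or its 10 kb flanks, for WT and Nan/+, with the number of genes in parentheses; a tick marks the mean of 10000 length-matched random lists and a filled point an adjusted p under 0.05. In each genotype 11 of 17 lists have filled points, housekeeping genes among them.

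Of the markers of other cell types of the fetal liver, 4 lists were not covered above chance in either genotype, under any setting tried. Hepatoblast markers had regions at 5 of 15 genes in WT and 3 of 15 in Nan/+, macrophage markers at 2 of 14 and 1 of 14, lymphoid and stem cell markers at 1 of 15 and 3 of 15, and endothelial markers at 2 of 11 and 5 of 11. Megakaryocyte markers had regions at 3 of 15 genes in WT and 9 of 15 in Nan/+, the latter at an adjusted p of 0.0520, and their Nan/+ call changed with the setting. They passed with equal list lengths by width (9 of 15, adjusted p = 0.00799) and with gene ends within 50 kb (12 of 15, adjusted p = 0.0444). In the other alternatives they did not pass, at adjusted p from 0.0595 to 0.202. Only 7083 Nan/+ regions were wider than 176 bp, so equal list lengths also kept regions tied at 176 bp, which width cannot rank. With the wider Nan/+ regions alone the count was 7 of 15 (random lists, adjusted p = 0.0595). Fli1, a megakaryocytic transcription factor, had 0 WT and 6 Nan/+ regions, whereas Gp1ba, the marker with the widest region, had 4 and 1. Of the genes reported as ectopic in Nan, 4 of 12 had a region in each list, and Hamp and Irf7 had 0 in both.

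The planned test of whether any list was split between the genotypes differently from other genes passed its threshold for 0 of 17 lists. Among other genes with a region in 1 genotype alone, 58.3% had it in Nan/+. The 1 list with an unadjusted p under 0.05 was the megakaryocyte markers, with 6 genes in Nan/+ alone and 0 in WT alone (Fisher's exact test, p = 0.0446, adjusted p = 0.758). With equal list lengths by width the counts were the same, and that share of other genes was 38.1%. Fisher's exact test then gave p = 0.00306 and adjusted p = 0.0520. Those equal lists include Nan/+ regions tied at the minimum width. Without any regions of that width, 5 genes had a region in Nan/+ alone and 1 in WT alone (Fisher's exact test, adjusted p = 0.223). All alternatives but equal list lengths gave adjusted p from 0.223 to 1. Against an even split, the exact sign test gave these markers p = 0.0312 and adjusted p = 0.531, and 0 of 17 lists passed. With at most 10 genes per list in 1 genotype alone, this test could miss moderate differences.

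**Figure D4:**
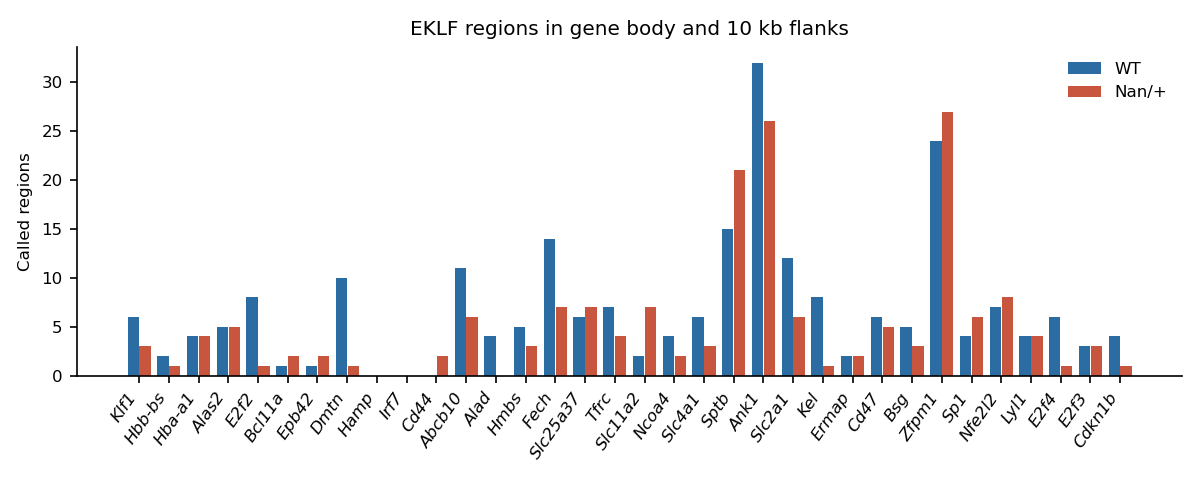
Number of called EKLF regions in the gene body and its 10 kb flanks in WT and Nan/+, for the always-named genes followed by the leading members, by region width, of the heme, iron, membrane, surface antigen, transcription factor and cell cycle lists. E2f2 stands at 8 and 1 and Dmtn at 10 and 1, whereas Zfpm1 stands at 24 and 27.

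Chromosomes were compared last. WT-only and Nan-only regions differed in their shares on 6 chromosomes (Fisher's exact test, adjusted p under 0.05), by small amounts. The lowest p belonged to chromosome 11, with 9.13% of WT-only and 7.46% of Nan-only regions (adjusted p = 0.000857). Regions cluster along chromosomes, so these p-values are too small.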

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

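Alternatives using region width, gene ends, merged regions or Nan/+ regions above the minimum width were chosen after seeing the data. No paired analysis was possible because each genotype has 1 list made from all its replicates, which also rules out leaving out replicates. Of 87 alternative values, 66 kept their direction and side of the threshold, or stayed within 1.5 times for counts; sharing stayed above random placement in every alternative run, from 14.3% to 34.7% of WT regions, and shared regions stayed more frequent at gene ends than the others. The gene-end difference between WT-only and Nan-only regions ranged from 17.7 points with Nan/+ regions above the minimum width to 31.99 with the widest 50% of each list. With a reciprocal overlap of 50% the width correlation was 0.731, which that rule raises by construction since it bounds the widths of a pair. With either gene end within 50 kb, genes with a region numbered 12187 in Nan/+ and 9042 in both, as the larger region implies. With equal list lengths by width, Nan-alone genes numbered 1869; with Nan/+ regions above the minimum width, WT-alone genes numbered 3310 and Nan-alone genes 1503, fewer Nan/+ regions entering by construction. With either gene end within 5 kb, WT-alone genes (2456) also exceeded Nan-alone genes (2208); the cause was not tested. Chromosomes past the threshold numbered 4 rather than 6 when genotype-only regions lay over 1 kb from the other list. Lists covered above chance numbered 10 or 11 in WT and 10 to 12 in Nan/+, but membership changed. In Nan/+ enucleation genes were lost with gene ends within 5 kb (adjusted p = 0.229), equal list lengths (0.0554) and regions above the minimum width (0.156), globin genes with unmatched random lists (0.200), and megakaryocyte markers were gained with equal list lengths (0.00799) and gene ends within 50 kb (0.0444). In WT housekeeping genes were lost with gene ends within 5 kb (0.0547). The other changes of call or size concern the WT share of region-gene pairs, described under the other observations. Alternatives by peak value, at transcription start sites and on motifs were not run, because the score is constant and strand and sequence were not used here. Depth was alike in the lists, but without tag counts per region a weak region cannot be told from a missing one.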

Other observations

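All tests in this part were chosen after the lists were examined. Over all protein-coding genes, those with the largest excess of regions differed in size between the genotypes, a difference that was not tested. For genes ranked by WT excess, the cut at 15 fell within a tie at an excess of 6. It left out the list members Slc2a1 (12 WT and 6 Nan/+ regions) and Tal1 (9 and 3). The 15 genes kept had a median length of 23.8 kb. They included 6 members of the fixed lists, Dmtn, Cpox, E2f2, Fech, Kel and Ank1. Those outside the lists included St6galnac3, the gene with the largest WT excess (17 WT and 5 Nan/+ regions), and Syt14 (12 and 3), which at 527 kb and 153 kb were long, as well as Lrrc29 (8 WT and 0 Nan/+ regions), Prdx2, which encodes an abundant red cell peroxiredoxin (7 and 1), and Nprl3 (9 and 2). The 15 with the largest Nan/+ excess had a median length of 296 kb and included Cmip (10 and 49), Asap1 (5 and 34), Kmt2c, a histone methyltransferase gene (1 and 23), Gse1 (27 and 51), Sox6, a repressor of embryonic globin and the 1 list member among them (23 and 45), and Gng2 (0 and 28).

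Lists that shared few positions still shared neighbourhoods. Over 2581 windows of 1 Mb the rank correlation of region number between the lists was 0.838, and 0.718 after adjustment for gene number, across windows that are not replicates. Chromosome 8 from 122 to 123 Mb, which holds Zfpm1 and Cbfa2t3, had 61 WT and 104 Nan/+ regions, of which 20 WT regions were shared. In the Nan/+ list 32.1% of regions with the lowest 20% of the numbers in their names were shared and 7.42% with the highest 20%. In WT the shares were 29.6% and 24.7%, with 22.6% to 23.0% in the classes between, so the WT share did not fall steadily. What these numbers rank was not established here.

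The Nan/+ list was longer than the WT list. Deeper sequencing is argued against by the summed ChIP tags, 0.984 of those in WT. The peak size setting stays open: among regions wider than 176 bp there were 0.838 Nan/+ regions per WT region, so the excess lies in regions of the minimum width, but the setting and the genotype cannot be told apart. A change in EKLF binding in Nan/+ embryos also stays open and was not tested.

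Few WT positions were called in Nan/+. Shifts of 10 to 50 kb left a mean overlap of 2.41% of WT regions against 24.5% observed. The overlapping positions thus exceeded what such shifts within a neighbourhood gave, although shifts also move regions off gene ends. They cannot bear on the 75.5% of WT regions without overlap, for which shared neighbourhoods without shared positions stay open. Loss of marginal WT calls stays open: 42.3% of the widest 25% of WT regions overlapped a Nan/+ region, but width is not a measured strength. A biological loss of these positions was not tested and stays open as well.

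A hypothesis that heme synthesis genes hold a larger part of their regions in WT than other genes was prompted by the counts at Cpox, Fech and similar genes and tested on the same lists, so it is not independent evidence. With 70 WT and 39 Nan/+ region-gene pairs, WT regions made up 64.2%, against 48.7% in lists matched on length and region number (random lists, adjusted p = 0.0187), and 51.0% against 38.9% for membrane genes (adjusted p = 0.0187). Both calls were lost in all 5 alternatives, where 0 lists passed. The excess for heme genes was 16.1 points with gene ends within 5 kb, 14.3 within 50 kb, 13.9 with equal list lengths, 9.65 with Nan/+ regions above the minimum width and 12.5 with regions within 2 kb merged, at adjusted p from 0.0595 to 0.207; for membrane genes it was 10.9, 7.21, 13.3, 10.3 and 8.86 points, at adjusted p from 0.0510 to 0.188. The direction held, but chance and the choice of gene region may account for the calls.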
